A study of Mus musculus with 18 samples.

How the data were processed

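The series measured mature miRNAs by small RNA sequencing in 18 mouse libraries, 9 MEF libraries with the miR-17~92 cluster overexpressed, floxed or deleted, 6 libraries of deleted MEF with an empty plasmid or with overexpressed miR-290~295, and 3 libraries of splenic B cells with the same 3 levels of miR-17~92. Per the labels' protocols, total RNA with added spike-ins was run on a gel, small RNAs were cut out, and libraries were made with the NEBNext small RNA kit. All 5 deposited tables were used, 2 for each MEF set, with and without spike-in scaling, and 1 for B cells. Left out were 12 columns of transformed values that cannot be matched to single replicates. The OV and fl/fl MEF count columns cannot be matched either, but their names show the group and they were used by group.

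The deposited values are signals, that is read counts per mature miRNA divided by 1 size factor per library. DESeq2 is named in the submitters' processing notes, without a version, and the aligner, the counting tool, the miRNA annotation and the genome build are not given in the sources used here. The tables list only miRNAs left after a filter by the submitters, whose threshold is not given in the sources used here. Each library's values were whole multiples of 1 step, in 100% of values within 0.0001, so whole reads were recovered from them. The tables with and without spike-ins differ by 1 factor per library. Per the file headers, the tables also hold DESeq2's rlog values, which are deposited on a log2 scale and were not used in any test.

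The tables list 1204 miRNAs in the miR-17~92 MEF set (1203 with spike-in scaling, 1187 in both), 1265 in the miR-290~295 set and 756 in B cells. MiRNAs with a mean of at least 10 normalized counts over a table's libraries were kept, 662, 840 and 476 of them. Total reads on listed miRNAs ran from 17191892 to 24920911, from 43164128 to 58911475 and from 10203586 to 10612256 per library in these sets. Differences were taken from the tables without spike-in scaling, which exist for all 3 sets and give changes relative to the typical miRNA. The spike-in table was an alternative for the MEF results, except for lists added after seeing the data and miRNAs it does not list. Sets were normalized separately, so limma, camera and permutation tests were made only within a set. Shares of reads were compared between sets only where the source of few reads was asked.

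The MEF comparisons were OV against fl/fl, d/d against fl/fl, OV against d/d, and miR-290~295 against Empty, 4 in all. Each used limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2 of the normalized count + 1, group as the only term, and Benjamini-Hochberg adjustment over all kept miRNAs at 0.05. The 9 libraries of the first set share 1 estimate of the spread. Every adjusted p of a single miRNA comes from this fit unless another is named.

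Lists of miRNAs were tested with limma's camera at a preset correlation of 0.01 between members, with Benjamini-Hochberg adjustment over the lists that kept at least 3 members. The 19 lists with entries begin with the miR-17~92, miR-106b~25, miR-106a~363, miR-290~295 and miR-322 to miR-503 clusters, the Dlk1-Dio3 and Sfmbt2 clusters and the let-7 family. Lists by cell type are mesenchymal and fibroblast, haematopoietic, epithelial, neural, muscle, and endothelial and liver miRNAs. The rest are MYC-repressed, p53-responsive and Microprocessor-independent miRNAs, and other polycistronic and monocistronic miRNAs. A further list, of miR-302~367, had no entries in any set. The miR-106a~363 and muscle lists kept too few members in MEF, and so did miR-290~295 in the miR-17~92 set. In B cells the miR-106a~363 list had 7 members, with medians of −0.10 in OV and −0.25 in d/d against fl/fl (−0.37 and −0.76 without a minimum), and the muscle list had miR-206-3p alone, at 179 normalized counts in d/d, 39.6 in fl/fl and 25.5 in OV. With the correlation between members estimated from the data, camera called 0 of these lists in each of the 4 comparisons, and 2, 3, 4 and 4 lists at an unadjusted p under 0.05. With fry, which asks whether a list's members move 1 way on balance and compares it with no other miRNA, 3, 13, 12 and 14 lists passed, against 4, 7, 7 and 7 with the preset correlation. A range beside a camera p is over alternatives that used camera, without fry.

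For each library the total of a cluster and the mean log2 value of other polycistronic minus monocistronic miRNAs were computed, and groups were compared by a two-sided exact permutation test, which cannot go below p = 0.1 with 3 libraries against 3. B cells have 1 library per group and were not tested. For each list the percentile of its median difference among 10000 random lists, matched on mean expression in 10 bins, is given as a description of those libraries. Where a group had no read of a miRNA, a bound was computed with 3 counts per library. Shares of reads in single libraries have Wilson 95% intervals.

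The miRNAs named were set by a rule. They are all kept members of the manipulated cluster, the 10 largest rises and 10 largest falls among miRNAs past the test whose libraries do not overlap between the groups, and up to 4 members of each list with the smallest adjusted p. Of 3 libraries against 3, chance gives no overlap for 10% of miRNAs. In B cells they are the miR-17~92 members and the 10 largest rises and falls in OV and in d/d against fl/fl, among miRNAs with a mean of at least 100. Other members of described lists in B cells were chosen after their values were seen. The comparisons, tests, lists, named-miRNA rule and alternatives were chosen before the data were examined, except where an alternative is said to be chosen after seeing the data.

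The alternatives were the spike-in table, re-centring of library medians, quantile scaling, no minimum or a minimum mean of 100, pseudocounts of 0.5 and 5, a robust fit, no trend, only the 2 groups compared in the fit, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, camera with an estimated correlation, fry, a block for replicate number, and leaving out each library in turn. Added after seeing the data were identical entries collapsed to 1, and other polycistronic miRNAs without Dlk1-Dio3 and without both Dlk1-Dio3 and Sfmbt2 members, whose list tests were adjusted over these added lists alone.

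MiRNA genes were placed on GRCm38 with the GENCODE annotation. It is not known to be the submitters' build. Of 1367 names listed, 1311 matched a miRNA gene, and with a window of 10 kb 441 lay at clustered and 860 at single genes, which served as another version of the polycistronic and monocistronic lists. MiRNAs with identical values in every library, and paralogs such as miR-106a-5p and miR-20b-5p, are treated as uncertain, since reads could be shared between them.

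The fit was tested on simulated data, with counts drawn from the real means and library sizes and 200 miRNAs changed. Of the 100 changed 2-fold it called 70% in the right direction for OV against fl/fl and 83%, 75% and 69% for the other comparisons in the order above, and of the 100 changed 4-fold 96%, 95%, 94% and 94%. False calls were 1.78%, 6.81%, 6.11% and 2.98% of calls among 662, 662, 662 and 840 miRNAs. Simulated miRNAs were drawn independently, with as many changed up as down. These shares therefore do not cover clusters that move together or a scaling that shifts all miRNAs. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.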

Results

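Small RNAs were sequenced from mouse cells that held the miR-17~92 cluster, an oncogenic polycistron activated by MYC, at 3 levels. The series has 18 libraries in 8 groups, 15 from mouse embryonic fibroblasts (MEF) and 3 from splenic B cells, and the labels give the Eu-myc strain for all of them. In both cell types the cluster was floxed and intact (fl/fl), deleted (d/d) or overexpressed (OV), in cells the labels call isogenic, with 3 libraries per MEF group and 1 per B-cell group. A separate MEF set took d/d cells with an empty plasmid (Empty) or with overexpressed miR-290~295, the main cluster of mouse embryonic stem cells, again with 3 libraries each. The libraries are called OV1, OV2 and OV4, FL3 to FL5 and DEL1 to DEL3 as in the deposited tables, and E1 to E3 and miR-290 1 to 3 in the other set. Nothing in the labels says whether replicates were separate cultures, so they may be technical. Reads on mature miRNAs ran from 17191892 to 24920911 per library in the miR-17~92 MEF set, from 43164128 to 58911475 in the miR-290~295 set and from 10203586 to 10612256 in B cells. Means are given with their SD and log2 changes with their SE.

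The first question was whether the groups held the cluster at the levels their labels give. The miR-17~92 genes lie on chromosome 14 from 115043671 to 115044506 in GRCm38, inside the non-coding host gene Mir17hg. Their mature products summed to 422223 ± 38195.9 normalized counts in OV, 79554.3 ± 15703.8 in fl/fl and 1600.6 ± 158.129 in d/d MEF (SD, n = 3 each). From mean log2 totals, OV was 5.36-fold above fl/fl, and d/d kept 2.03% of the fl/fl total. No library of one group overlapped another, and each two-sided exact permutation p was 0.1, the smallest that 3 libraries against 3 can give. With the spike-in scaled table the OV total was 5.89-fold the fl/fl one, and d/d kept 1.51%. Most of the total was miR-92a-3p, at 397214 ± 41641.8 in OV and 72377.9 ± 15995.6 in fl/fl.

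**Figure D1:**
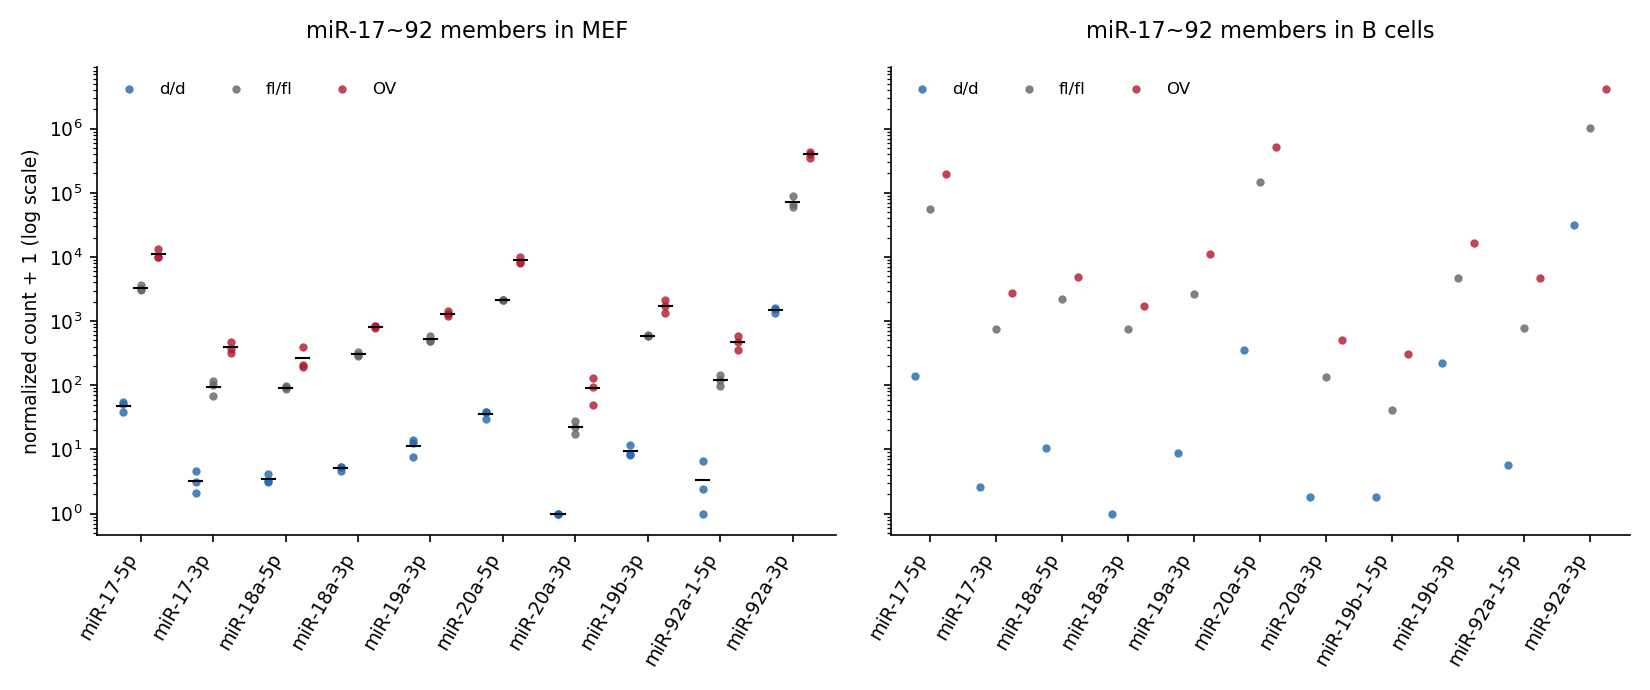
Normalized count + 1 (log axis) of each kept miR-17~92 member, with 1 point per library, in MEF (OV, fl/fl and d/d, 3 libraries each, black line the mean) and in B cells (1 library per group). Every member lies highest in OV and lowest in d/d, and miR-92a-3p is the most abundant, with a mean of 397214 in OV MEF.

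OV against fl/fl MEF asks what accompanies a moderate excess of the cluster, and whether its amount bears on miRNAs made from other clusters. All 10 measured members of miR-17~92 rose, by a list median of 1.83 on the log2 scale (camera adjusted p = 1.46e-08, and adjusted p = 0.109 with an estimated correlation, the highest of alternatives that began at 5.23e-12). MiR-92a-3p rose 5.55-fold (log2 2.47 ± 0.16, adjusted p = 1.18e-05), miR-20a-5p 4.13-fold (log2 2.05 ± 0.15, adjusted p = 1.72e-05) and miR-17-5p 3.34-fold (log2 1.74 ± 0.18, adjusted p = 0.000131). Of the other members, miR-19a-3p rose by 1.32 ± 0.22, miR-18a-5p and miR-18a-3p by 1.44, miR-19b-3p by 1.52 ± 0.20, miR-20a-3p by 1.94 ± 0.39 and miR-17-3p by 2.05 ± 0.32. Outside the cluster, camera called the lists of the imprinted Sfmbt2 intron and the X-linked miR-322 to miR-503 cluster upward and that of the imprinted Dlk1-Dio3 locus downward. With an estimated correlation these calls were lost, at an adjusted p = 0.162, 0.574 and 0.885. The paralogous miR-106b~25 cluster had no member past the test.

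In the Sfmbt2 cluster, 33 of 41 members rose and none fell (37 rose when adjusted over the list alone), with a median of 1.30. The call (camera adjusted p = 6.26e-19) was lost at an adjusted p = 0.162 with an estimated correlation, the highest of alternatives that began at 6.62e-24. Members that rose include miR-466g (1.58 ± 0.19), miR-467c-5p (1.29 ± 0.16) and miR-669c-5p (1.22 ± 0.15), each with an adjusted p of 0.000356. In the Dlk1-Dio3 clusters, 39 of 85 members fell and none rose (52 fell when adjusted over the list alone), with a median of −0.92. The camera call, at an adjusted p of 1.75e-11, was lost at an adjusted p = 0.885 with an estimated correlation, where alternatives began at 9.46e-16, and at 0.103 with fry. The list was lowest in OV4, where its total was 140361 normalized counts against 277914 in OV1 and 327415 in OV2, and without OV4 the median was −0.54 (adjusted p = 3.17e-10). MiR-434-5p fell from 28471 ± 3299 to 14769 ± 4459 (log2 −0.99 ± 0.20, adjusted p = 0.00504), and miR-369-5p and miR-485-5p each fell by 1.20. In the miR-322 to miR-503 cluster, whose products slow the cell cycle, 6 of 11 members rose and none fell, also 6 adjusted over the list alone, with a median of 0.41. Its camera call (adjusted p = 0.0171) was lost at 0.0546 with medians re-centred, at 0.0661 without OV4 and at an adjusted p = 0.574 with an estimated correlation, among alternatives that began at 0.00288. MiR-322-5p rose by 1.35 ± 0.21 and miR-503-5p by 1.10 ± 0.17.

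Single miRNAs with large rises were miR-129-5p, which is abundant in neurons (3.20-fold, log2 1.68 ± 0.15, adjusted p = 8.21e-05), and miR-146a-5p, a brake on NF-kappaB signalling. The latter rose from 1519 ± 77.0 to 4378 ± 801 (log2 1.51 ± 0.15, adjusted p = 9.72e-05). Among the least abundant, miR-205-5p rose by 2.00 ± 0.42, miR-466i-3p by 1.92 ± 0.36, miR-669p-3p by 1.96 ± 0.48 and miR-466a-3p by 1.69 ± 0.30. MiR-297a-3p, miR-297b-3p and miR-297c-3p have identical values in every library (log2 2.19 ± 0.36, and 1.46 with a pseudocount of 5) and cannot be told from each other. The paralogs miR-20b-5p (1.98 ± 0.52) and miR-106a-5p (1.68 ± 0.56) are uncertain, since their reads stayed near 0.476% and 1.07% of those of miR-20a-5p and miR-17-5p in OV, and near 0.463% and 1.10% in fl/fl. The epithelial miR-200b-3p, a repressor of ZEB factors, fell 5.90-fold, from 156 ± 4.42 to 25.9 ± 4.51 (log2 −2.56 ± 0.24, adjusted p = 8.89e-05). MiR-200b-3p also fell in d/d, and miR-129-5p and miR-205-5p also rose there, against the same fl/fl libraries. These changes are therefore not particular to an excess of the cluster. The CREB-responsive miR-212-5p fell from 714 ± 50.2 to 229 ± 33.0 (log2 −1.64 ± 0.15, adjusted p = 8.21e-05). Further falls were those of miR-187-5p (−2.23 ± 0.46), miR-1247-3p (−1.87 ± 0.38), miR-370-5p (−1.61 ± 0.36) and let-7c-1-3p (−1.45 ± 0.28). MiR-668-3p (−1.84 ± 0.46; −1.15 without OV4), miR-190a-5p (−1.77 ± 0.54), miR-1197-3p (−1.54 ± 0.42; −0.90 with a pseudocount of 5) and miR-665-3p (−1.43 ± 0.47; −0.77 without OV4) also fell. Not all of these rises and falls are separate results, since members of a cluster are transcribed together. At least miR-370-5p and miR-1197-3p belong to the Dlk1-Dio3 list and miR-669p-3p to the Sfmbt2 one. Other miRNAs named singly, here and below, may lie at these loci too. Calls that a single library or setting decides are those of miR-190a-5p (−1.15 without OV2), miR-1197-3p, miR-665-3p, miR-20b-5p, miR-106a-5p and miR-92a-1-5p. Their adjusted p rose to at most 0.0922, 0.0723, 0.118, 0.0580, 0.111 and 0.0722, from lowest values of 0.00311, 0.00575, 0.00933, 0.00181, 0.00262 and 0.00149 over their alternatives. MiR-92a-1-5p, at 1.93 ± 0.55, missed the threshold without OV1 (0.0592), FL4 (0.0722) or FL5 (0.0685) and with a pseudocount of 0.5 (0.0616), and miR-20b-5p without FL5 (0.0580). MiR-106a-5p missed it without OV1 (0.0941), OV2 (0.0560), OV4 (0.0834), FL3 (0.0967), FL4 (0.111) or FL5 (0.0887), with a pseudocount of 0.5 (0.0955) and without a minimum (0.0556), and miR-190a-5p without OV1 (0.0550), OV2 (0.0675), FL3 (0.0742), FL4 (0.0723) or FL5 (0.0922). MiR-1197-3p missed it without OV2 (0.0531), FL3 (0.0624) or FL4 (0.0723), and miR-665-3p without FL3 (0.118) or FL5 (0.113), in the spike-in table (0.0723) and without a minimum (0.0538).

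The other lists had no call in OV against fl/fl. Among other polycistronic miRNAs, 30 of 218 rose and 52 fell (57 fell and 30 rose adjusted over the list alone), with a median of −0.15 and an adjusted p of 0.0518. Its call was gained in the spike-in table, at 0.0439 and a median of −0.01. Without Dlk1-Dio3 members, an alternative chosen after seeing the data, 30 of 153 rose and 21 fell. The median was then 0.03, without a call (camera adjusted p = 0.771), so the downward lean rests on the Dlk1-Dio3 members. Of 118 monocistronic miRNAs, 16 rose and 18 fell (16 and 18 adjusted over the list alone), with a median of 0.02. The risers included miR-140-3p, a cartilage miRNA (1.18 ± 0.11), and miR-676-3p (1.43 ± 0.16). Of 26 mesenchymal and fibroblast miRNAs 2 rose and 6 fell, also when adjusted over the list alone, with miR-99a-5p at −1.26 ± 0.13, miR-199a-5p at −0.62 ± 0.11 and miR-152-3p at 0.58 ± 0.11. Of 12 neural miRNAs 4 rose and 2 fell (4 and 3 adjusted over the list alone), with miR-218-5p at −0.62 ± 0.11. Of 51 MYC-repressed miRNAs 2 rose and 3 fell (1 and 1 adjusted over the list alone), with miR-23a-5p at 1.20 ± 0.20. Of 21 let-7 family members 2 rose and 2 fell (1 and 2 adjusted over the list alone), with miR-98-3p at 0.80 ± 0.23. Of 9 haematopoietic miRNAs 2 rose and 1 fell, and of 4 epithelial ones 2 rose and 1 fell (2 and 2 adjusted over the list alone). No p53-responsive, Microprocessor-independent, endothelial and liver, or miR-106b~25 miRNA passed the limma test. The median was 0.17 for the p53-responsive list, 0.04 for the Microprocessor-independent one, −0.09 for the endothelial and liver one and −0.20 for miR-106b~25. Median and mean differ in sign for let-7 (0.03 and −0.02), haematopoietic (−0.17 and 0.12), epithelial (0.07 and −0.10), endothelial and liver (−0.09 and 0.08), MYC-repressed (−0.02 and 0.02) and p53-responsive miRNAs (0.17 and −0.01). In the spike-in table the medians turned to 0.05 for endothelial and liver and 0.12 for MYC-repressed miRNAs. The mesenchymal and fibroblast median turned there from −0.095 to 0.040. They were 0.16 for monocistronic, 0.30 for p53-responsive, 0.17 for Microprocessor-independent and for let-7, 0.20 for epithelial, −0.05 for haematopoietic and −0.06 for miR-106b~25 miRNAs.

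In all, 207 of 662 miRNAs passed limma with Benjamini-Hochberg adjustment, 103 higher and 104 lower in OV. The split depends on scaling: it was 112 higher and 44 lower in the spike-in table, where the median of all miRNAs moved from −0.07 to 0.07, and 83 higher and 153 lower with medians re-centred, at a median of −0.20. Without FL5 the count fell to 124, of which 72 were higher and 52 lower.

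**Figure D2:**
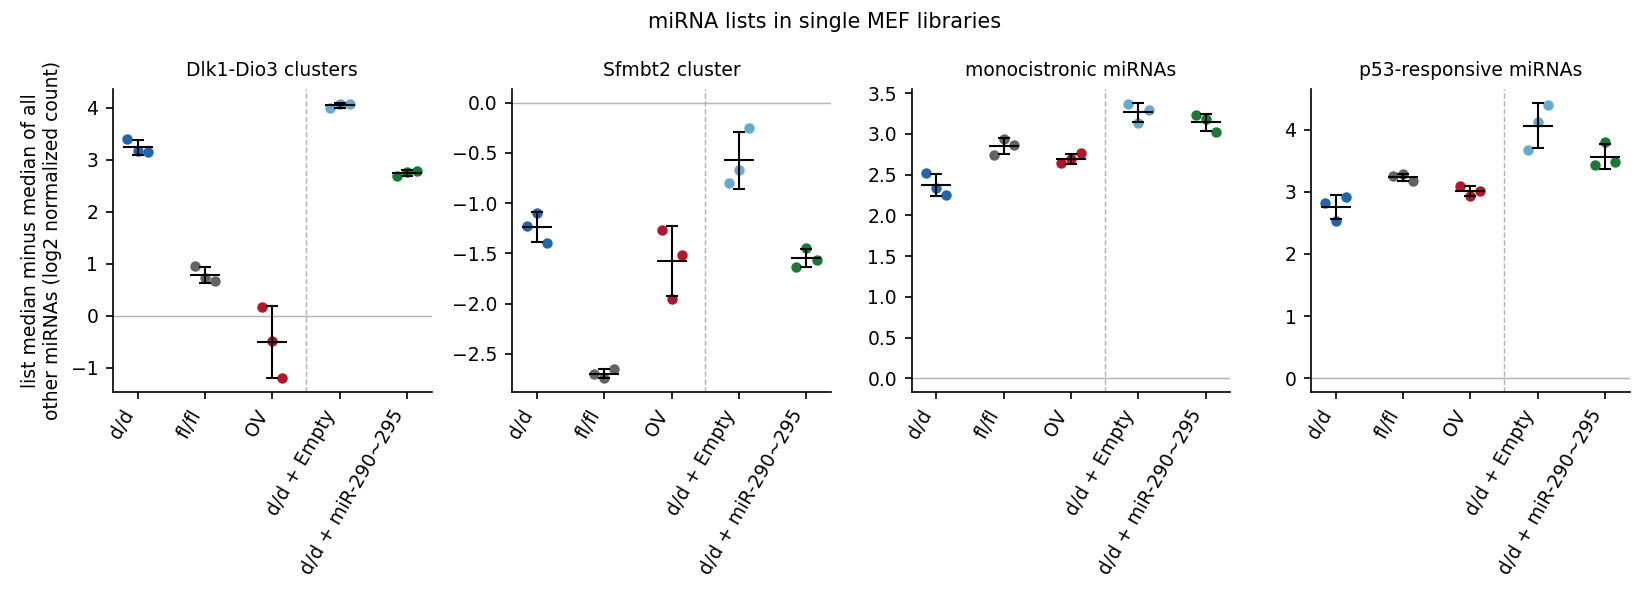
Median log2 value of each list minus the median of all other miRNAs (y axis, log2), with 1 point per library, a line at the group mean and bars of 1 SD, for the Dlk1-Dio3, Sfmbt2, monocistronic and p53-responsive lists in the 5 MEF groups; the dashed line parts sets that were normalized separately. The Dlk1-Dio3 list stands highest in d/d and lowest in OV within its set, and is lower in miR-290~295 than in Empty libraries, where its median change was −1.08.

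D/d against fl/fl MEF asks what accompanies loss of the cluster. All 10 members of miR-17~92 fell, with a list median of −5.58 (camera adjusted p = 8.67e-10, and adjusted p = 0.0773 with an estimated correlation, the highest of alternatives that began at 1.61e-14). MiR-17-5p fell 69.4-fold, from 3299 ± 357 to 46.9 ± 8.49 (log2 −6.12 ± 0.18, adjusted p = 1.24e-09), and miR-92a-3p fell 48.0-fold, to 1489 ± 143 (log2 −5.58 ± 0.16). MiR-19b-3p, miR-20a-5p, miR-18a-3p, miR-19a-3p and miR-92a-1-5p fell by 5.99, 5.92, 5.91, 5.57 and 5.57, and miR-17-3p and miR-18a-5p by 4.90 and 4.72. MiR-20a-3p had no read in any d/d library and lay at least 8.53-fold below its fl/fl level of 21.3 ± 4.99, taking 3 counts per library as the floor. Beyond the cluster, camera called the Dlk1-Dio3, Sfmbt2 and other polycistronic lists upward and the p53-responsive, MYC-repressed and monocistronic lists downward. None held with an estimated correlation, at an adjusted p = 0.216, 0.216, 0.359, 0.216, 0.359 and 0.184.

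In the Dlk1-Dio3 clusters 83 of 85 members rose and none fell, 83 also when adjusted over the list alone, with a median of 2.59. Camera's adjusted p of 6.50e-26 was lost at an adjusted p = 0.216 with an estimated correlation, the highest of alternatives that began at 6.55e-38. MiR-323-3p rose 11.6-fold, from 769 ± 7.43 to 8942 ± 509 (log2 3.54 ± 0.27, adjusted p = 4.38e-06), and miR-382-3p from 1151 ± 897 to 12080 ± 452 (log2 3.69 ± 0.51). MiR-487b-5p (4.88 ± 0.87; 3.16 with a pseudocount of 5), miR-758-3p (3.77 ± 0.30), miR-323-5p (3.76 ± 0.55), miR-341-5p (3.49 ± 0.40), miR-485-3p (3.03 ± 0.21) and miR-679-3p (2.89 ± 0.22) rose with them. In the Sfmbt2 cluster 37 of 41 members rose and none fell, 37 adjusted over the list alone, with a median of 1.45. The call (camera adjusted p = 3.32e-10) was lost at an adjusted p = 0.216 with an estimated correlation, the highest of alternatives that began at 8.86e-13. Its members miR-466f-3p, miR-467c-5p and miR-466g rose by 1.97 ± 0.25, 1.74 ± 0.16 and 1.71 ± 0.19. OV and d/d share the 3 fl/fl libraries against which this list's median was positive in both.

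Of 14 p53-responsive miRNAs 8 fell and none rose, 8 adjusted over the list alone, with a median of −0.58 (−1.01 in the spike-in table). Camera's adjusted p of 0.0181 was lost at an adjusted p = 0.216 with an estimated correlation, the highest of camera alternatives that began at 0.00282. Those that fell included miR-34c-5p (−0.90 ± 0.12) and miR-34b-5p (−0.87 ± 0.14), direct p53 targets, and miR-192-5p (−1.04 ± 0.11) and miR-194-5p (−1.02 ± 0.15). Of 51 MYC-repressed miRNAs 24 fell and 10 rose (24 and 11 adjusted over the list alone), with a median of −0.39 (−0.82 in the spike-in table and −0.67 with medians re-centred). The call (camera adjusted p = 0.0421) was lost at an adjusted p = 0.359 with an estimated correlation, the highest of camera alternatives that began at 0.0149. It was also lost without FL4 (0.0737) or DEL3 (0.0859) and with identical entries collapsed (0.0513), the last an alternative chosen after seeing the data. Among the members miR-30d-5p fell by 0.99 ± 0.08, miR-26a-5p by 1.02 ± 0.09, miR-30c-5p by 1.20 ± 0.13 and the growth-restraining let-7b-5p by 0.82 ± 0.11. Of 118 monocistronic miRNAs 50 fell and 21 rose (54 and 21 adjusted over the list alone), with a median of −0.37 (−0.80 in the spike-in table, and −0.65 with medians re-centred or quantile scaling). Camera's adjusted p of 0.0021 was lost with a minimum mean of 100 (0.0887, at −0.28) and at an adjusted p = 0.184 with an estimated correlation, the highest of camera alternatives that began at 0.000309. The list holds miR-218-5p, which fell 3.73-fold (log2 −1.90 ± 0.11, adjusted p = 6.78e-07), and miR-196a-5p, from the Hox clusters, which fell by 1.26 ± 0.11.

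Of 218 other polycistronic miRNAs 100 rose and 57 fell (101 and 60 adjusted over the list alone), with a median of 0.28 and a camera call upward (adjusted p = 0.0133). The call was lost at an adjusted p = 0.359 with an estimated correlation, where camera alternatives began at 0.00381. The median turned to −0.15 in the spike-in table and −0.01 with medians re-centred, and was 0.13 with quantile scaling and 0.16 with a minimum mean of 100. The sign rests on the imprinted loci, in an alternative chosen after seeing the data. Without Dlk1-Dio3 members the median was −0.23, with camera downward at an adjusted p of 0.0454 (adjusted p = 0.128 with an estimated correlation), and without Sfmbt2 members too it was −0.28, at 0.00857. With an estimated correlation the latter had an adjusted p = 0.0446, adjusted over the added lists alone. Its unadjusted camera p of 0.0223 was close to the 0.0230 of the monocistronic list, whose call was lost when adjusted over 16 lists. The reduced list is therefore not shown to be more stable than the lists fixed beforehand.

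Among single miRNAs, miR-483-5p, which lies in an Igf2 intron, rose from 14.8 ± 4.57 to 305 ± 12.8 (log2 4.32 ± 0.40, adjusted p = 1.14e-05), and miR-483-3p rose by 4.43 ± 0.75. MiR-6540-5p rose by 3.51 ± 0.23 and miR-3070-5p by 3.55 ± 0.70. MiR-378a-3p, from an intron of the metabolic coactivator gene Ppargc1b, fell 6.52-fold, from 30607 ± 1278 to 4698 ± 284 (log2 −2.70 ± 0.28, adjusted p = 2.33e-05), and its other arm miR-378a-5p fell by 2.90 ± 0.30. MiR-378c (−3.02 ± 0.27) and miR-378d (−2.66 ± 0.28) are near copies of miR-378a-3p and their reads cannot be parted from it with certainty. The neural miR-153-5p had no read in any d/d library and 43.3 ± 23.1 normalized counts in fl/fl. MiR-547-3p (−3.97 ± 0.41), miR-200b-3p (−3.49 ± 0.24), miR-218-1-3p (−2.86 ± 0.32) and miR-187-3p (−2.58 ± 0.22) fell, as did the uncertain miR-106a-5p (−3.73 ± 0.56). MiR-224-5p fell 2.82-fold, from 57141.4 ± 4256.16 to 20235.9 ± 931.626.

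The remaining lists had no camera call. In miR-106b~25, 4 of 6 members fell, 4 adjusted over the list alone, at a median of −0.58, with miR-25-3p at −0.68 ± 0.08. Of 21 let-7 miRNAs 10 fell and 7 rose, also when adjusted over the list alone, at a median of −0.43, with let-7k at −1.47 ± 0.14 and let-7c-5p at −0.75 ± 0.10. Of 12 neural miRNAs 6 fell and 1, miR-129-5p (1.18 ± 0.15), rose, at a median of −0.46. Of 4 epithelial miRNAs 3 fell and miR-205-5p rose (1.97 ± 0.42), at a median of −1.03. Of 3 endothelial and liver miRNAs 2 fell, the endothelial miR-126a-3p among them by 1.08 ± 0.11, at a median of −1.08. In the miR-322 to miR-503 list 3 of 11 rose and 2 fell at a median of 0.18, but miR-322-3p (0.31 ± 0.11) turned to −0.12 in the spike-in table. Of 26 mesenchymal miRNAs 8 fell and 5 rose (7 and 4 adjusted over the list alone), with miR-10b-5p up by 1.22 ± 0.15. Their median was 0.13 and their mean 0.04, while camera gave the direction as down. Of 9 haematopoietic miRNAs 3 rose, miR-342-5p among them (1.08 ± 0.17), and 1 fell, miR-155-5p (−0.68 ± 0.19), at a median of 0.19. Of 6 Microprocessor-independent miRNAs 2 rose and miR-1224-5p fell (−2.20 ± 0.37), at a median of 0.15. The counts of the neural, epithelial, endothelial and liver, miR-322 to miR-503, haematopoietic and Microprocessor-independent lists were the same adjusted over the list alone. In the spike-in table the medians turned to −0.25 for miR-322 to miR-503, −0.30 for mesenchymal, −0.24 for haematopoietic and −0.28 for Microprocessor-independent miRNAs. They were −1.01 for miR-106b~25, −0.86 for let-7 and −0.87 for neural miRNAs.

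Of 662 miRNAs 386 passed, 203 higher and 183 lower in d/d. In the spike-in table the split was 147 higher and 283 lower, with the median of all miRNAs at −0.39 in place of 0.02, and with medians re-centred it was 162 and 245, at a median of −0.27.

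OV against d/d MEF sets the most of the cluster against the least. Its 10 members rose by a median of 7.42 (camera adjusted p = 2.00e-10, and adjusted p = 0.0626 with an estimated correlation), and the total 264-fold (two-sided exact permutation p = 0.1). MiR-92a-3p rose 267-fold (log2 8.06 ± 0.16, adjusted p = 3.97e-11), miR-20a-5p by 7.96 ± 0.15, miR-17-5p by 7.86 ± 0.18, miR-19b-3p by 7.51 ± 0.20 and miR-92a-1-5p by 7.50 ± 0.55. MiR-18a-3p, miR-17-3p, miR-19a-3p and miR-18a-5p rose by 7.35, 6.95, 6.89 and 6.16. MiR-20a-3p, without a read in d/d, was at least 35.7-fold higher in OV (89.3 ± 39.4). Of 85 Dlk1-Dio3 miRNAs 84 fell and none rose (85 fell adjusted over the list alone), with a median of −3.51 and a camera call that was lost at an adjusted p = 0.178 with an estimated correlation. MiR-323-3p fell 23.2-fold, to 412 ± 169 (log2 −4.54 ± 0.27), and miR-434-5p fell 10.6-fold (log2 −3.41 ± 0.20, adjusted p = 4.40e-07). MiR-485-3p (−3.85 ± 0.21), miR-758-3p (−4.67 ± 0.30), miR-323-5p (−5.10 ± 0.55), miR-487b-5p (−4.67 ± 0.87; −3.04 with a pseudocount of 5), miR-1197-3p (−4.43 ± 0.42), miR-1188-5p (−4.26 ± 0.25) and miR-370-5p (−4.20 ± 0.36) fell as well. In the Sfmbt2 list 2 of 41 rose and 1 fell (1 and 0 adjusted over the list alone), with a median of −0.23 (0.32 in the spike-in table) and no camera call (adjusted p = 0.261).

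In OV against d/d camera called the monocistronic, p53-responsive, MYC-repressed and neural lists upward. None of these calls held with an estimated correlation, at an adjusted p = 0.108, 0.197, 0.327 and 0.178. Of 118 monocistronic miRNAs 59 rose and 18 fell (60 and 18 adjusted over the list alone), with a median of 0.45. MiR-146b-5p rose 5.62-fold (log2 2.49 ± 0.17, adjusted p = 1.13e-06) and miR-676-5p by 2.40 ± 0.18, whereas miR-149-5p fell by 1.80 ± 0.14. Of 14 p53-responsive miRNAs 7 rose and none fell, 7 adjusted over the list alone, with a median of 0.57. MiR-192-5p rose from 2658 ± 169 to 6167 ± 472 (log2 1.21 ± 0.11), and miR-194-5p, miR-34b-5p and miR-34c-5p rose by 1.25 ± 0.15, 1.09 ± 0.14 and 1.06 ± 0.12. Of 51 MYC-repressed miRNAs 22 rose and 5 fell, also when adjusted over the list alone, with a median of 0.30 and with miR-30d-5p, miR-26a-5p and miR-30c-5p up by 1.05 ± 0.08, 0.95 ± 0.09 and 1.23 ± 0.13. Of 12 neural miRNAs 8 rose and 2 fell, also when adjusted over the list alone, with a median of 1.04, and miR-218-5p, miR-338-5p and miR-218-1-3p rose by 1.28 ± 0.11, 2.46 ± 0.33 and 2.49 ± 0.32.

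Camera's adjusted p was 0.000412 for the monocistronic, 0.0450 for the p53-responsive, 0.0450 for the MYC-repressed and 0.0426 for the neural list, 5.22e-36 for Dlk1-Dio3 and 2.00e-10 for miR-17~92. With an estimated correlation the adjusted p = 0.108, 0.197, 0.327, 0.178, 0.178 and 0.0626, so all were lost. Their camera alternatives ranged from 0.000103 to 0.108, 0.0239 to 0.197, 0.0173 to 0.327, 0.0133 to 0.386, 1.42e-62 to 0.178 and 1.95e-16 to 0.0626. The p53-responsive, MYC-repressed and neural calls were also lost without OV1 (0.0810, 0.0810 and 0.0654) and the MYC-repressed one without DEL3 (0.0870). With a minimum mean of 100 the p53-responsive and neural calls were lost too, at 0.0726 and 0.386. In the spike-in table the medians were 1.02 for the monocistronic, 1.13 for the p53-responsive, 0.87 for the MYC-repressed and 1.57 for the neural list. The MYC-repressed median was 0.46 with medians re-centred, the p53-responsive one 0.36 without a minimum, and the neural one 0.61 without a minimum and 0.64 with a minimum mean of 100. Of 218 other polycistronic miRNAs 52 rose and 89 fell (54 and 90 adjusted over the list alone), with a camera call downward (adjusted p = 0.00321, and adjusted p = 0.327 with an estimated correlation, where alternatives began at 0.000522). Their median of −0.18 turned to 0.38 in the spike-in table and 0.07 with quantile scaling, and was −0.03 with medians re-centred and −0.07 with a minimum mean of 100. In the lists chosen after seeing the data it was 0.17 without Dlk1-Dio3 and 0.22 without Sfmbt2 too, at an adjusted p of 0.0280 for both, and 0.101 and 0.0835 with an estimated correlation.

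Single rises in OV against d/d included miR-92b-3p, which shares the seed of miR-92a (8.89-fold, log2 3.15 ± 0.22, adjusted p = 1.13e-06), miR-92b-5p (3.19 ± 0.25) and miR-1224-5p, a mirtron (3.18 ± 0.37). MiR-547-3p (4.52 ± 0.41), miR-378c (2.53 ± 0.27), miR-3473e (2.50 ± 0.29) and miR-224-5p (1.84 ± 0.10) rose, as did the uncertain miR-106a-5p (5.41 ± 0.56) and miR-20b-5p (4.41 ± 0.52; 2.89 with a pseudocount of 5). MiR-153-5p stood at 76.8 ± 36.3 in OV against no read in d/d. The Igf2-intronic miR-483-5p fell 35.8-fold (log2 −5.16 ± 0.40), miR-483-3p by 6.73 ± 0.75 and miR-3072-3p by 4.54 ± 0.87. In lists without a call, miR-146a-5p rose by 1.76 ± 0.15 (haematopoietic, 1 of 9 higher and 3 lower, median −0.08), miR-203-3p by 1.45 ± 0.22 (epithelial, 3 of 4 higher, median 0.84) and miR-126a-3p by 0.99 ± 0.11 (endothelial and liver, 2 of 3 higher, median 0.99). MiR-10b-5p fell by 1.81 ± 0.15 (mesenchymal, 3 of 26 higher and 4 lower, 2 and 4 adjusted over the list alone, median −0.06). MiR-450a-5p rose by 0.83 ± 0.13 (miR-322 to miR-503, 4 of 11 higher, 3 adjusted over the list alone, median 0.36), let-7k by 1.38 ± 0.14 (let-7, 9 of 21 higher and 4 lower, 10 and 4 adjusted over the list alone, median 0.30) and miR-106b-3p by 0.71 ± 0.10 (miR-106b~25, 2 of 6 higher, median 0.37). Of 6 Microprocessor-independent miRNAs 1 rose and 3 fell, with a median of −0.32, a mean of 0.18 and camera's direction down. Where no second count is given, the count adjusted over the list alone was the same. In the spike-in table the medians turned to 0.48 for haematopoietic, 0.51 for mesenchymal and 0.24 for Microprocessor-independent miRNAs. They were 0.94 for miR-106b~25, 0.87 for let-7, 0.93 for miR-322 to miR-503, 1.38 for epithelial and 1.55 for endothelial and liver miRNAs.

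Of 662 miRNAs 347 passed, 177 higher and 170 lower in OV than in d/d. The split was 333 and 120 in the spike-in table, with the median of all miRNAs at 0.60 in place of 0.02, and 231 and 138 with quantile scaling, at a median of 0.24.

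**Figure D3:**
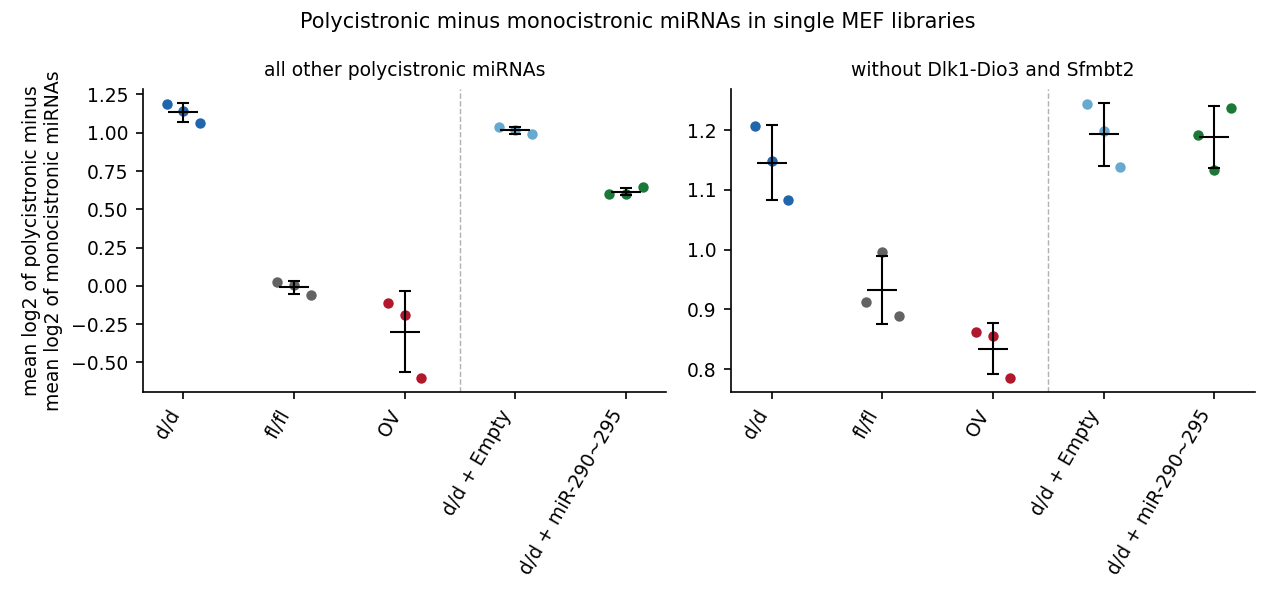
Mean log2 normalized count of other polycistronic miRNAs minus that of monocistronic miRNAs (y axis, log2), with 1 point per MEF library, lines at the group mean and bars of 1 SD, with all other polycistronic miRNAs on the left and without Dlk1-Dio3 and Sfmbt2 members on the right. On the left the d/d mean is 1.13 against −0.01 in fl/fl and −0.30 in OV, and on the right d/d exceeds fl/fl by 0.21.

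A score per library was taken as the mean log2 value of other polycistronic miRNAs minus that of monocistronic ones. It was −0.30 ± 0.26 in OV, −0.01 ± 0.04 in fl/fl and 1.13 ± 0.06 in d/d, and 1.01 ± 0.03 in Empty and 0.61 ± 0.02 in miR-290~295 libraries (SD, n = 3 each). The difference was 1.14 for d/d minus fl/fl, −0.29 for OV minus fl/fl, −1.43 for OV minus d/d and −0.40 for miR-290~295 minus Empty. Each had a two-sided exact permutation p of 0.1, the smallest possible here. The difference of OV from fl/fl was −0.14 without OV4, −0.18 with medians over members (exact permutation p = 0.3) and −0.12 with lists from the annotation (exact permutation p = 0.6), where 1 OV library lay above all fl/fl ones. That of miR-290~295 from Empty was −0.64 with medians and −0.68 with lists from the annotation. Without Dlk1-Dio3 miRNAs, an alternative chosen after seeing the data, the differences shrank to −0.01 for OV and 0.33 for d/d against fl/fl, −0.33 for OV against d/d and −0.07 for miR-290~295 against Empty. Without Sfmbt2 miRNAs as well they were −0.10, 0.21, −0.31 and −0.01. The exact permutation p was 0.9 for OV against fl/fl without Dlk1-Dio3 miRNAs, and 0.7 for miR-290~295 against Empty without both. Every other difference with these reduced lists had an exact permutation p of 0.1, and its libraries did not overlap. Without both, the score was 0.83 ± 0.04 in OV, 0.93 ± 0.06 in fl/fl and 1.15 ± 0.06 in d/d.

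MiR-290~295 against Empty, both in d/d MEF, asks what a different, seed-related cluster does when added to cells without miR-17~92. The miR-290~295 genes lie on chromosome 7 from 3218626 to 3220841 in GRCm38. Their products summed to 836220 ± 66576.9 normalized counts against 1829.34 ± 242.713 in Empty, a 459-fold difference (two-sided exact permutation p = 0.1), and 328-fold in the spike-in table. All 14 measured members rose, by a median of 8.61 (camera adjusted p = 8.95e-18, and adjusted p = 0.0515 with an estimated correlation). MiR-292a-5p was the most abundant, at 796149 ± 70936.6 against 1730.95 ± 218.656 (461-fold, log2 8.85 ± 0.14, adjusted p = 2.27e-10), and miR-293-3p rose 418-fold (log2 8.71 ± 0.21). MiR-291b-5p, miR-291a-5p, miR-293-5p, miR-290a-5p, miR-291a-3p, miR-292a-3p and miR-294-3p rose by 9.52, 9.07, 8.78, 8.69, 8.62, 8.60 and 8.35, and miR-295-3p and miR-295-5p by 7.60 and 7.39. MiR-290a-3p and miR-291b-3p had no read in Empty and were at least 11.3-fold and 24.5-fold higher, and miR-294-5p had none against 50.6 ± 8.64 normalized counts.

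**Figure D4:**
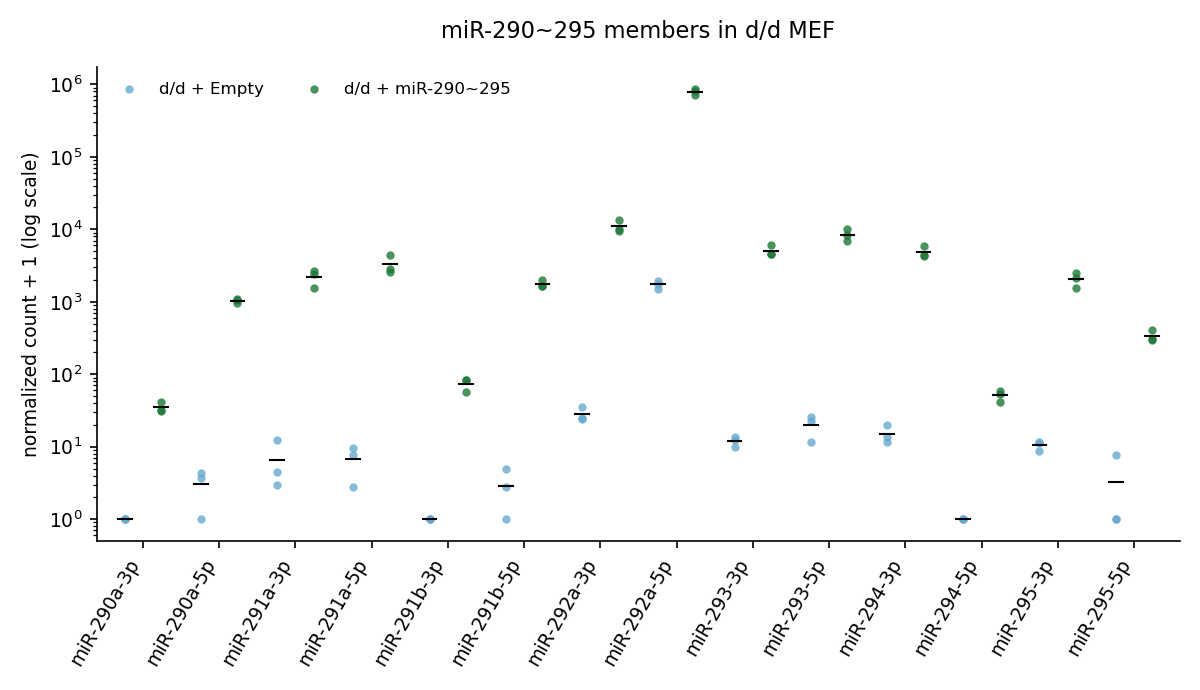
Normalized count + 1 (log axis) of each kept miR-290~295 member in Empty and miR-290~295 d/d MEF, with 1 point per library and 3 libraries per group. Every member is higher in all miR-290~295 libraries than in any Empty library, and miR-292a-5p reaches a mean of 796149.

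With miR-290~295 camera called the Dlk1-Dio3, Sfmbt2, miR-322 to miR-503, other polycistronic and miR-17~92 lists downward and the neural list upward. With an estimated correlation these calls were lost, at an adjusted p = 0.0723, 0.318, 0.415, 0.212, 0.191 and 0.208. Of 92 Dlk1-Dio3 miRNAs 78 fell and none rose (81 fell adjusted over the list alone), with a median of −1.08. MiR-127-3p, made antisense to the placental gene Rtl1, fell 2.40-fold (log2 −1.26 ± 0.12, adjusted p = 6.94e-05), miR-134-5p by 1.36 ± 0.12, miR-379-5p by 1.32 ± 0.13 and miR-370-3p by 1.38 ± 0.13. Of 51 Sfmbt2 miRNAs 33 fell and none rose (36 fell adjusted over the list alone), with a median of −0.84 (−1.32 in the spike-in table), and miR-669d-5p and miR-467e-5p fell by 1.37 ± 0.22 and 1.02 ± 0.16. MiR-669a-5p and miR-669p-5p share identical values (−1.18 ± 0.21). In miR-322 to miR-503, 6 of 11 fell and none rose, 6 adjusted over the list alone, with a median of −0.55 (−1.03 in the spike-in table). MiR-503-3p fell by 0.82 ± 0.14 and miR-322-3p by 0.81 ± 0.15. Of 233 other polycistronic miRNAs 95 fell and 25 rose (97 and 30 adjusted over the list alone), with a median of −0.42 (−0.90 in the spike-in table). Without Dlk1-Dio3 members, an alternative chosen after seeing the data, it was −0.08 and had no call (adjusted p = 0.808). The 3 miR-17~92 members measured in this set of d/d libraries fell, also when adjusted over the list alone, with a median of −2.69, and the source of these reads is not known. MiR-92a-3p went from 711 ± 172 in Empty to 147 ± 24.0 (4.76-fold lower, log2 −2.25 ± 0.22), miR-20a-5p fell by 3.98 ± 0.48 (−2.35 with a pseudocount of 5) and miR-17-5p by 2.69 ± 0.45. The total over all 6 listed miR-17~92 entries, kept or not, went from 774.599 ± 172.959 to 153.662 ± 21.4564 normalized counts (log2 −2.32, two-sided exact permutation p = 0.1).

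Of 12 neural miRNAs 7 rose and 1 fell, also when adjusted over the list alone, at a median of 0.72 (0.24 in the spike-in table). MiR-218-5p rose from 19833 ± 1434 to 59100 ± 5917 (log2 1.57 ± 0.13, adjusted p = 4.12e-05), miR-129-5p by 1.19 ± 0.11 and miR-9-3p, of neural progenitors, by 1.55 ± 0.27. Camera's adjusted p was 8.95e-18 for miR-290~295, 9.01e-25 for Dlk1-Dio3, 4.00e-10 for Sfmbt2, 2.78e-06 for other polycistronic, 0.00674 for miR-322 to miR-503, 0.00492 for miR-17~92 and 0.00419 for neural miRNAs. With an estimated correlation they were lost at an adjusted p = 0.0515, 0.0723, 0.318, 0.212, 0.415, 0.191 and 0.208. Each was the highest of camera alternatives that began at 6.91e-32, 2.83e-29, 2.61e-11, 4.14e-07, 0.00173, 0.00141 and 0.00255.

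Among single miRNAs, miR-6540-5p rose 14.7-fold, from 1319 ± 461 to 18749 ± 3363 (log2 3.87 ± 0.25, adjusted p = 6.10e-06), and miR-6540-3p by 2.83 ± 0.25. MiR-222-3p, a repressor of the cell-cycle inhibitor p27, rose 3.77-fold (log2 1.91 ± 0.31), miR-222-5p by 1.47 ± 0.14 and miR-196a-5p by 1.76 ± 0.15. MiR-670-5p, miR-218-1-3p, miR-130b-5p, miR-7117-5p and miR-449c-5p rose by 2.53 ± 0.47, 2.37 ± 0.29, 1.99 ± 0.39, 1.98 ± 0.45 and 1.89 ± 0.24. The immune-regulatory miR-146a-5p fell 4.56-fold, from 3680 ± 493 to 815 ± 175 (log2 −2.19 ± 0.20, adjusted p = 6.27e-05), and the epithelial miR-205-5p by 2.33 ± 0.28. MiR-6238, miR-465b-5p, miR-881-3p, miR-871-3p, miR-135a-2-3p and miR-1247-3p fell by 3.84 ± 0.70, 3.53 ± 0.62, 3.11 ± 0.50, 2.75 ± 0.45, 2.60 ± 0.36 and 2.54 ± 0.36. With a pseudocount of 5 the values were −2.10 for miR-6238, −2.30 for miR-465b-5p and −1.75 for miR-871-3p. MiR-12185-5p (1.87 ± 0.46), miR-135b-5p (1.82 ± 0.57), miR-470-5p (−2.77 ± 0.71) and miR-465c-5p (−2.69 ± 0.87) passed but depend on single libraries or settings, with adjusted p ranges over alternatives of 0.00783 to 0.0512, 0.0206 to 0.0905, 0.00136 to 0.0501 and 0.00464 to 0.114. With that pseudocount miR-135b-5p stood at 1.20, miR-470-5p at −1.73 and miR-465c-5p at −1.78. MiR-12185-5p was lost without miR-290 3 (0.0512), miR-470-5p without E2 (0.0501) and miR-465c-5p without E2 (0.114), E3 (0.0728), miR-290 1 (0.0567) or miR-290 2 (0.0573, at −1.61). MiR-135b-5p was lost with quantile scaling (0.0741) and without E1 (0.0599), E2 (0.0517), miR-290 1 (0.0905), miR-290 2 (0.0883) or miR-290 3 (0.05002).

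The mesenchymal list, with 13 of 27 lower and 1 higher (14 and 1 adjusted over the list alone) and a median of −0.46, had no call (adjusted p = 0.0886, and 0.0446 in the spike-in table). Within it the smooth-muscle pair miR-143-3p and miR-145a-5p fell by 0.92 ± 0.15 and 1.35 ± 0.24, and the 1 that rose was miR-31-5p (1.10 ± 0.15). The p53-responsive list, which holds the same pair, had 6 of 14 lower at a median of −0.19, and 3 of 9 haematopoietic miRNAs fell at a median of −0.35. Of 56 MYC-repressed miRNAs 9 rose and 2 fell (5 and 2 adjusted over the list alone) at a median of 0.04. Of 7 Microprocessor-independent ones 3 rose, 4 adjusted over the list alone, at a median of 0.94, but miR-877-3p and miR-702-3p (0.97 ± 0.20 and 0.96 ± 0.24) lost their calls in the spike-in table, with an adjusted p of 0.131 and 0.199. Of 126 monocistronic miRNAs 26 rose and 21 fell (24 and 21 adjusted over the list alone) at a median of 0.04. Of 23 let-7 miRNAs 4 rose, 1 adjusted over the list alone, at a median of 0.22, and let-7e-3p (0.47 ± 0.14) turned to −0.01 in the spike-in table. Of 5 epithelial miRNAs 1 rose and 1 fell at a median of 0.40 and a mean of −0.13. No miR-106b~25 or endothelial and liver miRNA passed limma, at medians of 0.06 and −0.35. The spike-in table turned the medians to −0.27 for let-7, −0.44 for MYC-repressed, −0.45 for monocistronic, −0.43 for miR-106b~25 and −0.08 for epithelial miRNAs. It gave −0.67 for p53-responsive, −0.95 for mesenchymal, −0.81 for haematopoietic, −0.84 for endothelial and liver and 0.46 for Microprocessor-independent miRNAs. Of 840 miRNAs 327 passed, 140 higher and 187 lower, and in the spike-in table the split was 56 and 331, with the median of all miRNAs at −0.46 in place of 0.02.

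In B cells, with 1 library per group and so no replicate check, miR-17~92 took 0.378% of reads in d/d, 12.6% in fl/fl and 36.3% in OV (Wilson 95% intervals 0.375 to 0.382, 12.5 to 12.6 and 36.3 to 36.3). MiR-92a-3p was 4.04-fold, miR-20a-5p 3.52-fold, miR-17-5p 3.51-fold, miR-19b-3p 3.49-fold, miR-19a-3p 4.20-fold and miR-18a-5p 2.26-fold higher in OV than in fl/fl. The less abundant miR-19b-1-5p, miR-92a-1-5p, miR-20a-3p, miR-17-3p and miR-18a-3p were 7.65-fold, 5.96-fold, 3.76-fold, 3.57-fold and 2.28-fold higher. In d/d miR-17-5p stood at 0.250% of its fl/fl level, miR-92a-3p at 2.98% and miR-19b-3p at 4.70%, and miR-18a-3p had no read and lay at least 312-fold lower. The other members stood at 0.209% to 2.01%. The intervals and floors cover counting error only. The miR-322 to miR-503 cluster was the list furthest above random ones in OV after miR-17~92, with 11 of 11 members higher, a median of 1.35 and the 100th percentile of 10000 random lists matched on level. Among its members miR-503-3p went from 77.3 to 259 normalized counts, miR-322-3p was higher by 1.52 and miR-450a-5p by 1.36. MiR-486a-5p, an erythroid miRNA, and miR-30a-3p were higher by 1.16 and 1.13, while the p53-induced miR-34c-5p was lower, at 648 against 1345, and miR-8114, miR-505-5p and miR-103-3p stood at −1.23, −1.23 and −0.87.

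**Figure D5:**
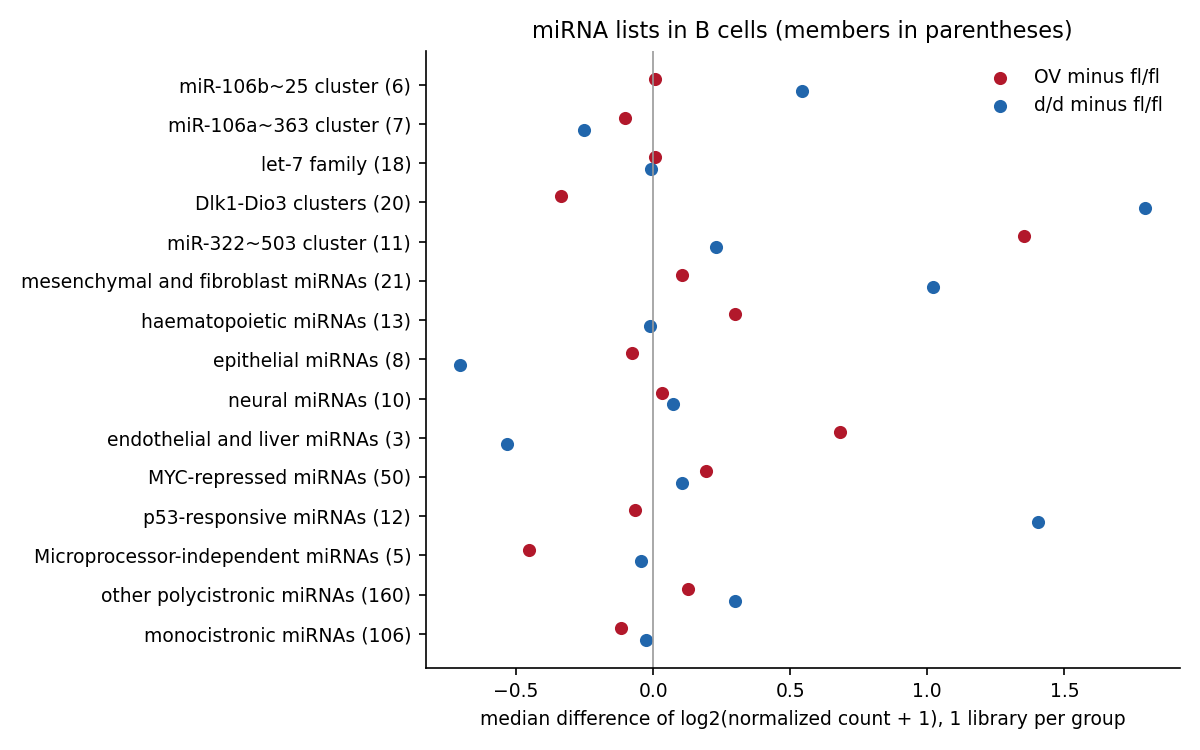
Median log2 difference of each list (x axis, log2) between OV and fl/fl and between d/d and fl/fl B cells, with 1 library per group and 1 point per list and difference. MiR-322 to miR-503 stands at 1.35 in OV, and the Dlk1-Dio3 clusters, p53-responsive miRNAs, whose value turns to −0.03 with a minimum mean of 100, and mesenchymal miRNAs stand at 1.80, 1.40 and 1.02 in d/d.

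In the d/d B-cell library 20 of 20 Dlk1-Dio3 miRNAs were higher than in fl/fl, with a median of 1.80 at percentile 100. This median was 1.40 with a minimum mean of 100 and 1.42 without a minimum. In OV it was −0.34 at percentile 7 (−0.71 with a minimum mean of 100, and −0.19 without a minimum). Mesenchymal miRNAs were higher in 18 of 21 (median 1.02, percentile 100, and 0.71 with a minimum mean of 100), among them miR-199a-3p by 2.13. The paralogous miR-106b~25 cluster was higher in 6 of 6 (median 0.54, percentile 99.1). The p53-responsive list stood at 1.40, with miR-34c-5p at 5277 against 1345, but at −0.03 with a minimum mean of 100. MiR-222-3p and miR-221-3p were 15.2-fold and 14.3-fold higher, miR-183-5p 9.37-fold, and miR-182-5p, miR-129-5p and miR-125a-5p by 2.84, 2.89 and 2.68. MiR-100-5p was 15.9-fold lower, at 2104 against 33416, miR-9-5p 14.7-fold lower, and miR-27a-5p and miR-181d-5p stood at −2.50 and −1.91. The score of other polycistronic minus monocistronic miRNAs was −0.51 in d/d, −1.01 in fl/fl and −0.83 in OV.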

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

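All tests in this part but the one on sequencing depth were chosen only after the result was seen.

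The p53-responsive miRNAs stood out because they differed in direction between the cell types: their median difference between d/d and fl/fl was 1.40 in B cells, with 1 library per group, and −0.58 in MEF. The difference between the cell types was not tested, and the B-cell value was −0.03 when miRNAs were required to have a mean of 100.

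The first pattern weighed is the higher Dlk1-Dio3 level in d/d than in fl/fl MEF. Library scaling multiplies a library by 1 factor, which nearly cancels from the list's median minus that of all other miRNAs. Spike-in scaling is therefore no separate check of this measure. With it the measure was 3.26 ± 0.126 in d/d and 0.802 ± 0.156 in fl/fl (SD, n = 3 each). Scaling alone could not give this difference of 2.45. The list's own median change does depend on scaling, at 2.59 without and 2.16 with spike-ins. For sequencing depth, libraries thinned to 17191892 reads kept a median change of 2.59 (2.56 to 2.61 over 20 draws, and 2.59 before thinning). The deepest library had only 24920911 reads, so thinning could hardly have changed the median and decides little. At similar depth, the list held 13.7% of the 17884099 reads of DEL3 and 2.56% of the 18609610 reads of FL3. A shift of all polycistronic miRNAs alike is argued against by those outside the Dlk1-Dio3 and Sfmbt2 clusters, which rose relative to monocistronic ones by 0.213 (two-sided exact permutation p = 0.1), where the Dlk1-Dio3 list rose by 3.06. What stays open is a difference between the cell lines at this imprinted locus, which cannot be told apart from an effect of the deletion because each genotype is 1 set of 3 libraries, although the list also moved, by −1.08, between miR-290~295 and Empty libraries, both from d/d cells.

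The second pattern is the reads left for a cluster where it is deleted or was not added. Reads of miR-290~295 in Empty libraries may come from the miR-290~295 libraries, and 1 of 14 members lay outside the counting interval of a pooled share of 0.219%. This check is weak, since miR-292a-5p, with 5226 reads in Empty, largely sets the pooled share. MiR-290a-3p, miR-291b-3p and miR-294-5p were expected at only 0.226, 0.488 and 0.337 reads. Any source that carries all members alike would give the same picture, so the source stays open. Expression in d/d cells is argued against by a level of miR-292a-5p in Empty at least 17.4 times that in any d/d library of the other set (28.8 to 39.9 against 1.01 to 1.65 RPM, reads scaled to the same total in every library). In d/d MEF, mature sequences also made by paralogous genes are argued against for the miR-17~92 reads: miR-92a-3p kept 2.06% and miR-19b-3p 1.42% of the fl/fl level against 1.56% for members made by this cluster alone, ratios of 1.31 and 0.909. Cells that kept the cluster stay open there, as the shares of 3 members with enough reads differed by 1.39 times, which reads passing between libraries would give too. In the d/d B-cell library paralogous genes may explain part of the reads, since miR-92a-3p kept 2.98% and miR-19b-3p 4.70% of the fl/fl level against 0.243% for the other members, 12.3 and 19.3 times as much.

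The third pattern is the higher level of mesenchymal and Dlk1-Dio3 miRNAs in the d/d than in the fl/fl B-cell library. Reads of the d/d MEF libraries counted there are argued against, because the share of 0.106% seen for miR-541-5p, the most abundant Dlk1-Dio3 miRNA of d/d MEF, would explain 9.45% of the rise of the median member among 39. Stromal cells in the sample stay open: the mesenchymal median of 1.02 lay at percentile 100 of matched random lists, but with 1 library such cells cannot be told apart from an effect of the deletion. The haematopoietic median stood at −0.01, and at 0.03 with medians re-centred.

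Among the 10 ways to split the 6 libraries of each comparison into groups of 3, 1 of 10 gave as many calls as the real one in each of the 4 comparisons, namely the real one. With only its own libraries in the fit the real split gave 156 calls for OV against fl/fl, 425 for d/d against fl/fl, 312 for OV against d/d and 327 for miR-290~295 against Empty. The highest other split gave 0 in each, and 10 splits are too few for a share under 0.05.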

How the results depend on the processing

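Of all values recomputed under an alternative, 224 were counts, scores, totals or B-cell medians of miR-17~92 that answer a comparison, and 215 of these kept their direction and, in the case of counts, stayed within the limit set beforehand, and B-cell medians within the counting interval. Scores and totals were held to direction alone. A library's scaling nearly cancels from the score, so the spike-in table could hardly turn it. The number kept therefore says little about how stable the sizes are. Without Dlk1-Dio3 and Sfmbt2 members the score difference shrank from 1.14 to 0.21 in d/d against fl/fl. In miR-290~295 against Empty it went from −0.40 to −0.01, and in OV against d/d from −1.43 to −0.31. In OV against fl/fl it went from −0.29 to −0.10, and to −0.01 without Dlk1-Dio3 members alone. Alternatives chosen after seeing the data were the collapsed entries and the reduced polycistronic lists. With an estimated correlation camera called 0 of the lists fixed beforehand in each comparison, and with fry 13, 12 and 14 lists in d/d against fl/fl, OV against d/d and miR-290~295 against Empty, where the preset correlation gave 7 each. These tests differ in what they ask. Leaving out each library in turn gave counts of 124 to 233 for OV against fl/fl (207 in all, and 124 without FL5), 342 to 365 for d/d against fl/fl, 305 to 343 for OV against d/d and 224 to 380 for miR-290~295 against Empty. The lists called ranged over 3 to 5, 6 to 7, 4 to 7 and 7 to 9, with 4 without OV1 in OV against d/d. The score ranged over −0.39 to −0.14, 1.11 to 1.17, −1.53 to −1.28 and −0.41 to −0.39, and cluster totals on the log2 scale over 2.32 to 2.58, −5.73 to −5.47, 7.96 to 8.11 and 8.74 to 8.93. The cause was not tested. In MEF the median of other polycistronic miRNAs turned sign in the spike-in table, from 0.28 to −0.15 in d/d against fl/fl and from −0.18 to 0.38 in OV against d/d, while camera kept its direction and call, and medians of several lists without a call turned too. B-cell medians that turned sign beyond the counting interval with a minimum mean of 100 were −0.027 for p53-responsive miRNAs in d/d against fl/fl (1.40 before) and 0.067 for other polycistronic miRNAs in OV against d/d (−0.11 before), where fewer miRNAs were left. Of the remaining values 1983 kept their call or size, 75 lost the call in the same direction and 20 moved by more than the counting interval. The counts with edgeR were 107 higher and 75 lower, 206 and 185, 184 and 166, and 129 and 198, and with DESeq2 107 and 130, 205 and 197, 175 and 175, and 154 and 194. The median of all miRNAs moved to −0.20 and 0.18 with quantile scaling of d/d against fl/fl and re-centring of OV against d/d.

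No paired analysis was possible in the miR-17~92 MEF set, whose OV and fl/fl columns cannot be matched to replicate numbers, or in B cells, with 1 library per group. In the miR-290~295 set the replicate number as a block gave 298 calls (327 without it, 286 shared) and 7 lists, and a sign-flip over pairs p of 0.25, the smallest possible, for the score difference of −0.40 and the total difference of 8.84. Same-numbered libraries correlated at 0.28, 0.01 and −0.26, and only number 1 correlated best with its own, so the numbers are not taken as pairs. Depth limits the least abundant miRNAs, for which 3 counts per library are the floor.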

Other observations

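All tests in this part were chosen only after the result was seen, and none of them is offered as an explanation.

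In B cells, single libraries give values for well-known lymphocyte miRNAs. MiR-155-5p, a miRNA of activated lymphocytes, and the B-lineage miR-181a-5p were near their fl/fl level in d/d B cells, at 469 against 597 and 31351 against 25435 normalized counts. MiR-150-5p, a brake on MYB in mature lymphocytes, had 8.73 against 62.2, and miR-146a-5p 21957 against 5514. MiR-21a-5p had 463477 normalized counts in d/d, 412388 in fl/fl and 335548 in OV B cells. The miR-106b~25 cluster, a paralog of miR-17~92 within the replication gene Mcm7, had 403289, 284979 and 285979. None of these has a replicate, and the values were chosen after they were seen.

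Between OV and d/d, each against fl/fl, 57 of 651 miRNAs rose in both, 31 fell in both, 15 rose in OV and fell in d/d, and 53 fell in OV and rose in d/d. Independent lists of these sizes would give 29.0, 27.6, 24.7 and 32.4. Without the Dlk1-Dio3 and Sfmbt2 clusters the counts among 525 were 26, 31, 15 and 14, where independent lists would give 9.49, 21.4, 19.8 and 10.3. Part of any excess may come from the shared fl/fl libraries, which are too few to split, and the count of OV calls was 124 without FL5. Across miRNAs, which are not independent replicates, Pearson's r was −0.10 and Spearman's rho −0.04. Simulated groups without any effect against those controls gave r = 0.51 over 100 draws, and a covariance of 0.06 where −0.10 was observed. Without the Dlk1-Dio3 and Sfmbt2 clusters r was 0.09, rho 0.18 and the covariance 0.06, near that of the draws, which had kept both clusters. The shared controls alone could give such a covariance, so the counts above are not taken as a shared response.

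D/d against fl/fl and miR-290~295 against Empty share no library. Of 647 miRNAs tested in both, 119 rose in d/d and fell with miR-290~295, where independent lists would give 52.4. Across miRNAs r was −0.42 and rho −0.40. Most of this came from the Dlk1-Dio3 and Sfmbt2 clusters, whose members are transcribed together: without them 15 of 521 did so, where independent lists would give 9.56, with r = 0.01 and rho = 0.00. OV against fl/fl and miR-290~295 against Empty had 55 miRNAs lower in both, where independent lists would give 26.8, and 40 higher in OV and lower with miR-290~295, where they would give 23.5, with r = 0.07 and rho = 0.12. Without these clusters the counts were 18 and 14, where independent lists would give 7.49 and 6.68. There 20 also rose in both and 16 fell in OV and rose with miR-290~295, where they would give 11.8 and 13.2. Every direction thus lay above independent lists, with r = 0.00 and rho = 0.02, so no common or opposed direction was seen.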
